A study of Homo sapiens with 16 samples.

How the data were processed

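Gene expression was measured in primary human epidermal keratinocytes on 16 single-colour Affymetrix whole-transcript arrays, 1 array per sample. Per the labels' protocols, cells at passage 5 had been expanded in a growth medium with 5 ng/ml epidermal growth factor (EGF) and 50 ug/ml bovine pituitary extract, were 50% or 100% confluent at the start, and then received basal medium alone (vehicle) or basal medium with 10 ng/ml EGF for 48 h, with 1 medium change at 24 h. The 4 groups hold 4 arrays each. RNA was isolated with RNA Stat-60 and labelled with biotin, per the labels' protocols.

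The deposited values are log2 expression values, 1 per probe set and array, made by the authors in dChip with the 5th percentile of region as background, per the series' design text. The log2 unit was inferred from the values, which lie between 0 and 14.67 with 2 decimals. The normalization between arrays, the summarisation model and the genome build are not given in the sources used here, so no coordinates are printed. The design text describes a choice of genes by a fold threshold of 1.5 between the untreated densities, a two-way analysis of variance, Benjamini-Hochberg control at 0.05 and Tukey comparisons. Those steps were rerun as an alternative.

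The table has 33252 rows, of which 21214 are listed in the probe annotation and 12038 are not. Rows naming exactly 1 gene numbered 19460, and 1754 named several genes. For each gene the row with the highest mean over the 16 arrays was kept, which left 18417 genes. More than 1 row was available for 769 genes. For some called genes another row went the opposite way at an unadjusted limma p under 0.05. These were 17 genes for density in vehicle, 4 for EGF at 50% confluence and 15 for EGF at 100% confluence. Gene symbols were updated or kept through Entrez identifiers for 19429 rows. Values of 0 on at least 1 array occurred in 363 rows and in 2 of the genes tested. No further normalization was applied.

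A linear model with 4 group means was fitted to all 16 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (12 residual and 5.06 prior degrees of freedom). Tested were density in vehicle (100% minus 50% confluence), density with EGF, EGF minus vehicle at each density, and the interaction, that is the EGF change at 100% minus that at 50% confluence. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 18417 genes. Errors beside a log2 change are standard errors of the difference between group means. All tests were two-sided. The p-values measure only the spread between these samples, since no label says whether replicates are separate cultures, and replicate numbers were not treated as pairs.

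Before the data were examined, 27 gene lists were written for keratinocyte differentiation, growth, EGF receptor signalling, metabolism and stress and for other cell types a skin-derived culture could hold. Each list was tested in each contrast with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, then with the correlation between genes estimated from the data. Counts of list members called over all genes stand beside counts adjusted over the list alone. The named genes followed a rule fixed at the same time: 14 fixed genes given whatever their value; for density in vehicle and EGF at each density, the 6 largest rises and 6 largest falls among called genes whose 4 values in one group all lay above the 4 of the other; the 5 largest changes in each direction for the interaction; and the 2 members with the largest change in each list whose test passed. The fixed genes aside, the rule passed over Y-linked genes, XIST, genes also named by rows of several genes and numbered members of their families. The largest changes are thus the largest among the remaining genes. TP63 and AREG, both among the fixed genes, have no row naming them alone and were not analysed here. Genes added after their values were seen are named as such.

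The fit was tested on simulated data with 200 changed genes among 18417. For EGF at 100% confluence it recovered 34 of 67 genes changed 1.5-fold, 58 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 8 false calls. The simulated arrays had independent noise around the same gene means in all groups, without a density change or an error shared by arrays. The data gave 3713 called genes in this contrast, so these rates need not hold there. The number of arrays limits the precision.

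Alternatives were quantile normalization, centring on array medians, adding 16 on the linear scale before the logarithm, leaving out the dimmest 25% or the dimmer 50% of genes, testing all rows, a fold threshold of 1.5, a replicate block, a variance trend with robust moderation, array weights, fits of only the groups compared, the authors' two-way analysis of variance with Tukey tests, and each array left out in turn. Because the contrasts for density in vehicle and EGF at 100% confluence share the confluent vehicle arrays, their relation was also computed with those arrays split 2 and 2 in all 6 ways and against 100 draws of simulated unchanged groups. Rows naming no single gene were left out of the gene counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.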

Results

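The data describe primary human epidermal keratinocytes, the main cell type of the epidermis, at subconfluent (50%) or full (100%) density, kept for 48 h in basal medium without (vehicle) or with EGF, a growth factor that acts through the EGF receptor. Each of the 4 groups was measured on 4 arrays, and levels are given on the log2 scale as mean ± SD (n = 4). Changes are differences of group means on the log2 scale ± SE.

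The median log2 value of the arrays lay between 6.87 and 7.13, and no 2 arrays were identical (0 pairs). Spearman correlations across all genes ranged from 0.957 to 0.995 between arrays of a group and from 0.873 to 0.984 between arrays of different groups. The first principal component held 61.0% of the variance and the second 12.1%. The array nearest to the third confluent EGF array (EGF_100 replicate 3) was vehicle_100 replicate 1 (rho 0.967), not another EGF_100 array. Leaving out EGF_100 replicate 3, an alternative singled out after seeing the data, gave counts of genes called of 7963 for density in vehicle, 5148 for density with EGF, 1941 for EGF at 50% confluence, 4415 for EGF at 100% confluence and 1874 for the interaction.

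Density in vehicle compares confluent with subconfluent cells in the absence of EGF. Markers of keratinocyte differentiation rose steeply. KRT1 (probe set 7963491), a keratin of the suprabasal layers, went from 8.15 ± 0.19 to 13.57 ± 0.04, a rise of 5.42 ± 0.12 (adjusted p = 1.17e-15), and its partner KRT10 rose by 4.50 ± 0.12. FLG, which encodes filaggrin of the cornified layer, rose by 5.79 ± 0.11 and LORICRIN (probe set 7905563), a main protein of the cornified envelope, by 5.47 ± 0.24. IVL and TGM1, an envelope precursor and the enzyme that crosslinks it, rose by 2.96 and 2.42. Other large rises were those of the amino acid transporter SLC6A14 (6.29 ± 0.14), FLG2 (6.04), SPTSSB, a subunit of serine palmitoyltransferase (5.78), KRT23 (5.77) and LCE3D, a late cornified envelope gene (5.71). Large falls were those of the protease inhibitor TFPI2 (-4.58 ± 0.17), the interferon-induced IFIT3 (-4.34) and IFIT1 (-3.72), EMP3 (-4.27), the intermediate filament gene VIM (-4.02) and THBS2 (-3.74). The proliferation marker MKI67 fell by 1.97 ± 0.12 and EGFR by 0.58 ± 0.09. HBEGF, which encodes an EGF receptor ligand, was at 1.51 (adjusted p = 1.08e-08) and DUSP6, a phosphatase of ERK, at -0.52 (0.00381). KRT14 and KRT5, the keratins of the basal layer, had high values on all arrays (KRT14 13.74 in subconfluent and 13.82 in confluent vehicle cells) and were not called (adjusted p = 0.455 and 0.61). KRT10 (13.84) and KRT1 (13.57) reached similar values in confluent vehicle cells, and saturation of these probes was not measured.

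**Figure D1:**
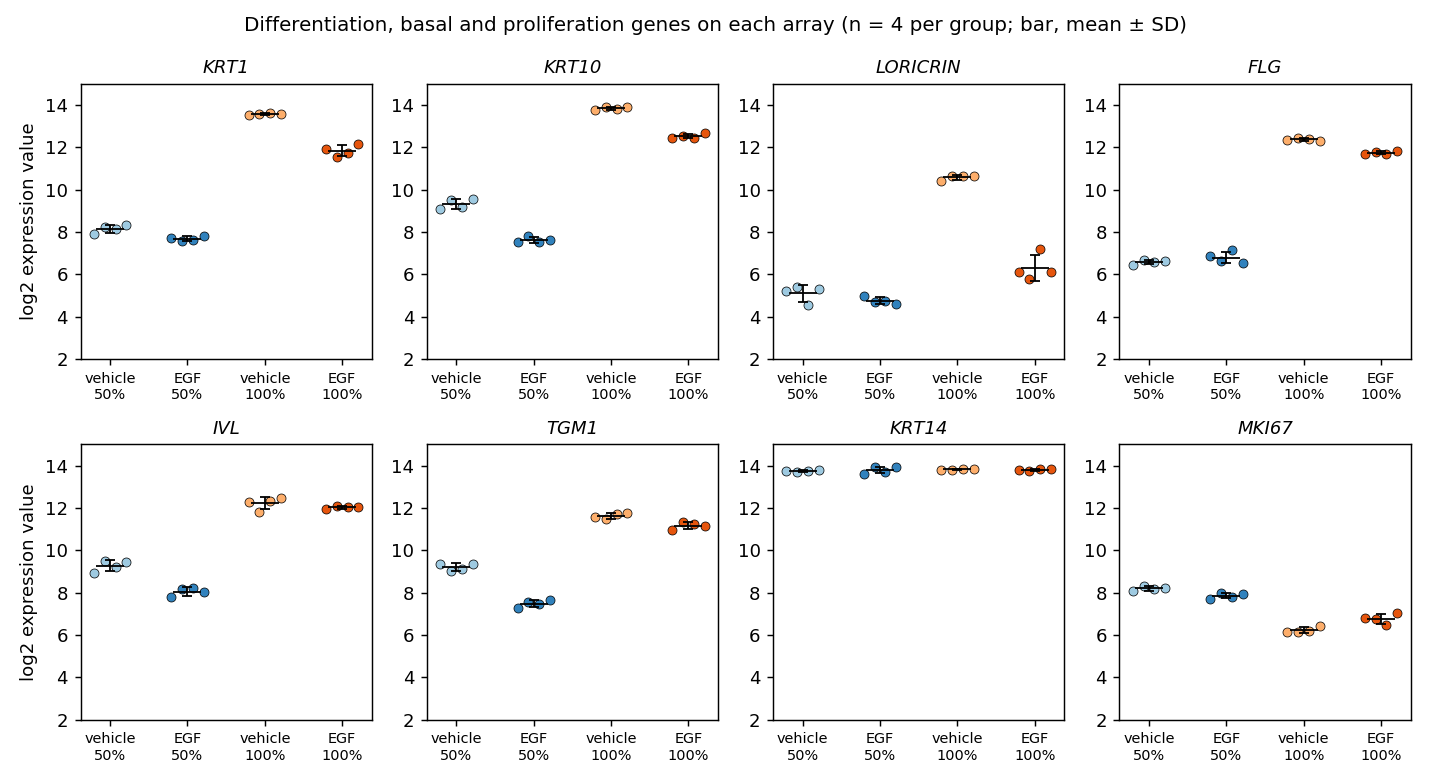
Log2 expression value (y axis) of 8 genes on each of the 16 arrays in the 4 groups (x axis); each point is an array and the bars are mean ± SD (n = 4). KRT1 lay at 8.15 in subconfluent and 13.57 in confluent vehicle cells, LORICRIN fell from 10.58 to 6.30 with EGF at 100% confluence, and KRT14 stayed between 13.74 and 13.82 in the group means.

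The differentiation lists rose together. Of 47 measured genes of the cornified envelope and late differentiation, 43 rose and 2 fell (43 and 2 adjusted over the list alone, median 2.21, camera adjusted p = 8.08e-26, and 0.000442 with an estimated correlation), the 2 that fell being TGM2 and PADI3, named after their values were seen. Among 25 suprabasal keratins and early differentiation genes 22 rose (22 adjusted over the list alone, median 3.55, adjusted p = 4.43e-21, and 2.35e-05 with an estimated correlation), including HOPX (5.61). Of 29 epidermal lipid barrier genes, 25 rose and 1 fell (25 and 1 adjusted over the list alone, median 2.27, adjusted p = 1.06e-19, and 5.58e-06 with an estimated correlation), with LIPM at 5.57 and SDR9C7 at 4.74. Kallikreins and their inhibitors, which act in shedding of the cornified layer, rose in 18 of 20 (18 adjusted over the list alone, median 3.49, adjusted p = 3.11e-19, and 0.000108 with an estimated correlation), with WFDC12 at 5.70 and SERPINB12 at 5.19. Of 22 antimicrobial and S100 genes 18 rose and 1 fell (18 and 1 adjusted over the list alone, median 1.91, adjusted p = 8.44e-12, and 0.00149 with an estimated correlation), among them S100A7 (4.78) and IL36RN (4.03). Differentiation transcription factors rose in 18 of 25 and fell in 1 (18 and 1 adjusted over the list alone, adjusted p = 2.83e-09, and 0.000491 with an estimated correlation), with RORA at 3.95. Desmosome and tight junction genes rose in 14 of 22 and fell in 3 (16 and 4 adjusted over the list alone, adjusted p = 0.00177), with CLDN4 at 2.25. The list had adjusted p = 0.0649 with an estimated correlation.

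Growth and wound genes fell. Among 35 genes of the G2 and M phase of the cell cycle 34 fell (35 adjusted over the list alone, median -1.87, adjusted p = 8.08e-26, and 0.0158 with an estimated correlation), with DLGAP5 at -3.04 and ANLN at -2.71. S phase and DNA replication genes fell in 27 of 39 and rose in 2 (27 and 3 adjusted over the list alone, adjusted p = 1.8e-10, and 0.00442 with an estimated correlation), with TYMS at -2.67 and MCM6 at -2.23. Basal keratinocyte and hemidesmosome genes, which anchor cells to the basement membrane, fell in 17 of 22 and rose in 1 (18 and 1 adjusted over the list alone, adjusted p = 1.62e-10, and 0.0167 with an estimated correlation), with ITGA2 at -2.32 and KRT15 at -2.19. Wound response and migration genes fell in 20 of 26 and rose in 1 (20 and 2 adjusted over the list alone, adjusted p = 8.44e-13, and 0.0177 with an estimated correlation). Type I interferon response genes fell in 19 of 27 and rose in 2 (20 and 3 adjusted over the list alone, median -1.42, adjusted p = 2.83e-09, and 0.0273 with an estimated correlation). Genes of the epithelial to mesenchymal transition fell in 10 of 18 and rose in 2 (10 and 2 adjusted over the list alone, adjusted p = 1.03e-05, and 0.0177 with an estimated correlation), with SPARC at -3.01. Fatty acid synthesis genes fell in 13 of 22 and rose in 3 (13 and 3 adjusted over the list alone, adjusted p = 0.000472), with FADS2 at -3.44, and YAP and TAZ targets fell in 14 of 24 and rose in 4 (14 and 5 adjusted over the list alone, adjusted p = 0.0058), with AXL at -2.69. For both of these lists the adjusted p = 0.171 with an estimated correlation, and the YAP and TAZ call ended without the dimmer 50% of genes (adjusted p = 0.111). For lists, leaving out dim genes, array weights and 16 added were settings chosen after seeing the data. In all, 7515 of 18417 genes were called, 3816 higher and 3699 lower in confluent cells. The lower genes were the more numerous with quantile normalization (3284 of 7311 higher), median centring (3627 of 7365), all rows (5200 of 10483) and changes of at least 1.5-fold (2071 higher). The same held without the dimmest 25% (3199 of 6750) or dimmer 50% of genes (2268 of 5220), and without vehicle_50 replicate 4 (3372 of 6817) or vehicle_100 replicate 1 (3308 of 6769), replicate 2 (3130 of 6502) or replicate 3 (3365 of 6825). At least 1.5-fold changes numbered 4295, and the authors' two-way layout with Tukey tests, run only on genes past its 1.5-fold choice, called 4112.

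With EGF present, the density comparison gave many of the same genes. KRT1 rose by 4.15 ± 0.12, KRT10 by 4.90, FLG by 4.95 and TGM1 by 3.69, while LORICRIN rose by only 1.55 ± 0.24. CEACAM6, a cell adhesion molecule, rose by 5.25 ± 0.22 (adjusted p = 2.46e-12), against 0.54 ± 0.22 in vehicle (not called, adjusted p = 0.0594; called at 0.0491 with median centring, 0.0468 without the dimmest 25% of genes, 0.0466 without vehicle_50 replicate 2, 0.0466 without vehicle_100 replicate 3 and 0.0363 without EGF_100 replicate 2). MKI67 fell by 1.10 and VIM fell by 2.44. IVL was at 3.98, HBEGF at -0.92 and DUSP6 at -1.14, all called, while EGFR (0.05), KRT14 (0.01) and KRT5 (-0.08) were not called. Of 47 cornified envelope genes 42 rose and 2 fell (43 and 2 adjusted over the list alone, adjusted p = 3.03e-37, and 7.09e-05 with an estimated correlation), and of 35 G2 and M phase genes 31 fell (33 adjusted over the list alone, adjusted p = 1.32e-22, and 0.0226 with an estimated correlation). Interferon response genes fell in 12 of 27 and rose in 2 (15 and 2 adjusted over the list alone, adjusted p = 0.000266). This call had adjusted p = 0.170 with an estimated correlation. Cholesterol synthesis genes fell in 12 of 19 and rose in 2 (13 and 2 adjusted over the list alone, adjusted p = 1.28e-05). The test then gave adjusted p = 0.174 with an estimated correlation. The 5587 genes called were 2170 higher and 3417 lower at 100% confluence; 1597 of the genes higher and 2564 of those lower were called the same way in vehicle, where independent calls would share 449.6 and 686.3. The count was 2879 for changes of at least 1.5-fold and 9071 with array weights.

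EGF at 50% confluence asks what the growth factor does in subconfluent cells. The chemokine gene CXCL14 fell by 3.24 ± 0.20, from 11 ± 0.22 to 7.76 ± 0.12 (adjusted p = 4.31e-08). The desmosomal cadherins DSG1 and DSC1 fell by 2.90 ± 0.14 and 2.34 ± 0.14, CRABP2, a retinoic acid binding protein, by 1.97, EPGN, a ligand of the EGF family, by 1.92 and IGFBP3 by 1.91. The interstitial collagenase gene MMP1 rose by 2.14 ± 0.19, C10orf55 by 1.86, G0S2, an inhibitor of lipolysis, by 1.76, TMEM200A by 1.58, the pseudogene ROCK1P1 by 1.41 and SMOC1 by 1.40. KRT10, TGM1 and IVL fell by 1.72, 1.73 and 1.21. The values of FLG and LORICRIN were 0.21 and -0.36 and were not called. EGFR (-0.05), KRT14 (0.06) and KRT5 (0.03) were not called either, nor was MKI67 (-0.34, adjusted p = 0.0997; called at 0.0444 without EGF_100 replicate 3). KRT1 fell by 0.48, a call lost without vehicle_50 replicate 2 (adjusted p = 0.0637), vehicle_50 replicate 3 (0.0553), vehicle_50 replicate 4 (0.0721), EGF_50 replicate 2 (0.0783) or EGF_50 replicate 3 (0.0835), and with arrays centred on their medians (0.0537).

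Suprabasal keratins and early differentiation genes fell in 15 of 25 and rose in 2 (16 and 2 adjusted over the list alone, median -0.76, adjusted p = 1.4e-15, and 0.0002 with an estimated correlation). Epidermal lipid barrier genes fell in 4 of 29 (9 fell and 1 rose adjusted over the list alone, adjusted p = 0.000749, and 0.0137 with an estimated correlation), including SULT2B1 (-0.87) and CERS3 (-0.85). Kallikreins and their inhibitors fell in 5 of 20 (6 adjusted over the list alone, adjusted p = 6.15e-05, and 0.0343 with an estimated correlation), including KLK5 (-1.11) and SLPI (-0.73). Wound response and migration genes rose in 10 of 26 and fell in 4 (11 and 4 adjusted over the list alone, adjusted p = 0.00288), with INHBA at 1.19. The list had adjusted p = 0.340 with an estimated correlation. EGFR and ERK feedback targets rose in 11 of 35 and fell in 1 (13 and 3 adjusted over the list alone, adjusted p = 0.000749), with PHLDA1 at 0.85 and DUSP6 at 0.73. This call had adjusted p = 0.302 with an estimated correlation. Heat shock and unfolded protein response genes rose in 8 of 21 and fell in 1 (11 and 3 adjusted over the list alone, adjusted p = 0.000805), with the chaperone HSPA5 at 0.89 and HERPUD1 at 0.99. The test then gave adjusted p = 0.248 with an estimated correlation. Desmosome and tight junction genes fell in 4 of 22 and rose in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.00272), with CLDN1 at -1.60 and DSC2 at -0.67. The list had adjusted p = 0.151 with an estimated correlation. Cornified envelope genes fell in 9 of 47 and rose in 3 (11 and 4 adjusted over the list alone, adjusted p = 0.0166). This call had adjusted p = 0.340 with an estimated correlation, 0.0795 without the dimmer 50% of genes, 0.0763 without vehicle_50 replicate 2 and 0.0805 without EGF_50 replicate 4. The list median was -0.05, and -0.01 and -0.02 without those 2 arrays. Differentiation transcription factors fell in 4 of 25 and rose in 2 (6 and 3 adjusted over the list alone, adjusted p = 0.00907). The list had adjusted p = 0.0973 with an estimated correlation. Cholesterol synthesis genes rose in 5 of 19 (10 rose and 1 fell adjusted over the list alone, adjusted p = 0.000956). The test then gave adjusted p = 0.340 with an estimated correlation. Interferon response genes fell in 2 of 27 (2 adjusted over the list alone, median -0.22, adjusted p = 0.000467), with IFI44L at -1.0. With an estimated correlation the adjusted p = 0.248. Of 39 S phase and DNA replication genes none was called, and the list leaned down (median -0.13, adjusted p = 0.0218). The S phase list call had adjusted p = 0.333 with an estimated correlation. It was also lost with quantile normalization (0.0554), array weights (0.0523), without the dimmer 50% of genes (0.388), and without vehicle_50 replicate 3 (0.138) or replicate 4 (0.0604) or EGF_50 replicate 1 (0.132) or replicate 3 (0.0583). Of 18417 genes 1263 were called, 690 higher and 573 lower with EGF; 565 changed at least 1.5-fold, and array weights gave 3112. The count was 748 without vehicle_50 replicate 1, 780 without vehicle_50 replicate 3, 719 without EGF_50 replicate 2, 625 without EGF_50 replicate 3, 764 without EGF_50 replicate 4 and 1941 without EGF_100 replicate 3. The lower genes were the more numerous without vehicle_50 replicate 1 (336 higher) and without EGF_50 replicate 2 (343), replicate 3 (310) or replicate 4 (333). The same held with all rows (719 of 1595 higher) and without the dimmer 50% of genes (648 of 1299).

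**Figure D2:**
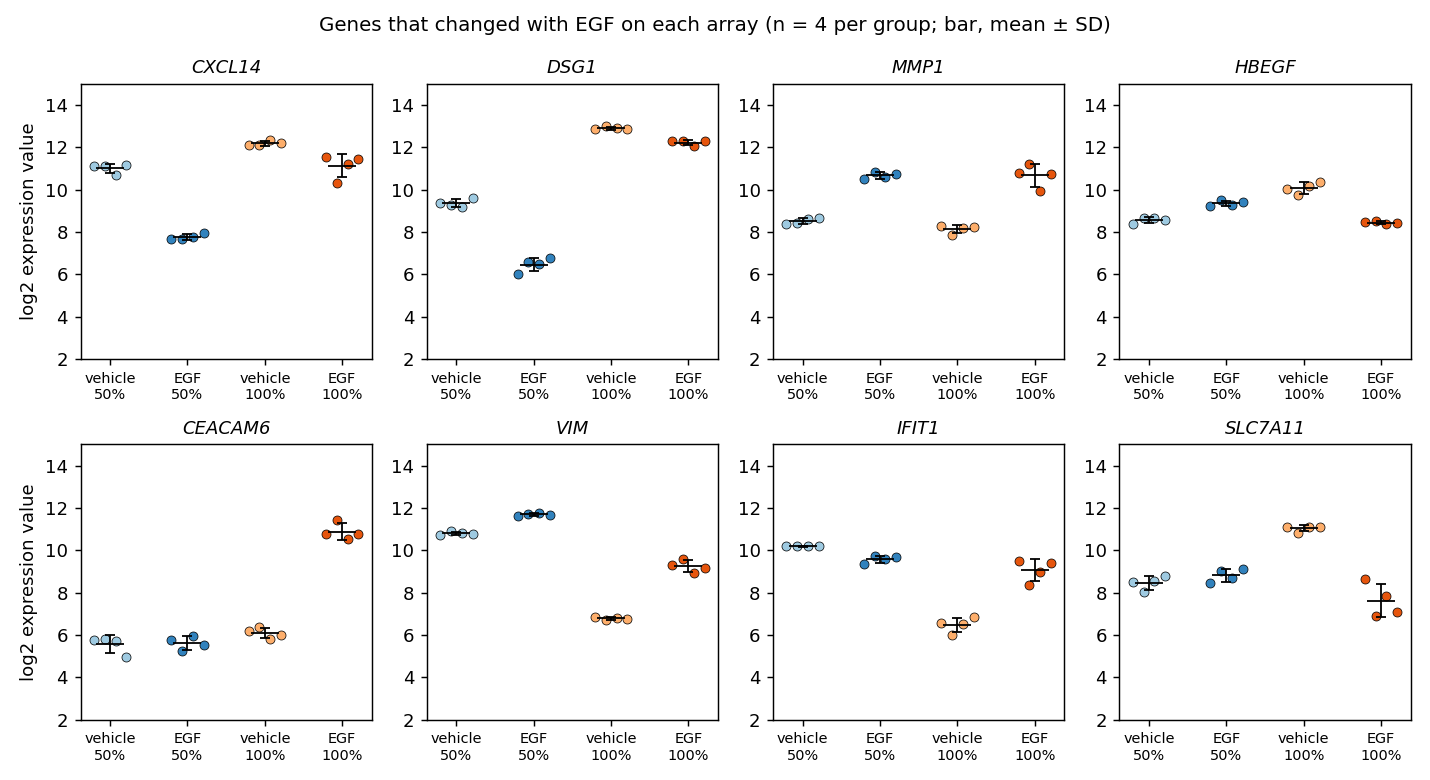
Log2 expression value (y axis) of 8 genes on each of the 16 arrays in the 4 groups (x axis); each point is an array and the bars are mean ± SD (n = 4). CXCL14 fell from 11 to 7.76 with EGF at 50% confluence, and CEACAM6 rose from 6.10 to 10.88 with EGF at 100% confluence.

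EGF at 100% confluence asks the same of confluent cells. LORICRIN fell by 4.29 ± 0.24, from 10.58 ± 0.11 to 6.30 ± 0.63 (adjusted p = 2.88e-09), and STC2, a secreted glycoprotein, fell by 4.17 ± 0.37. SLC7A11, the cystine and glutamate exchanger, fell by 3.42, THAP3 by 3.26, the lipase gene LIPN by 3.19 and the fatty acid receptor gene CD36 by 3.12. CEACAM6 (probe set 8029098) rose by 4.78 ± 0.22 to 10.88 ± 0.39. The interferon-induced IFIT1 rose by 2.60, MMP1 by 2.53, the ectonucleotidase gene NT5E by 2.51, VIM by 2.47 and MMP10 by 2.38. KRT1 fell by 1.75, KRT10 by 1.32, FLG by 0.63 and TGM1 by 0.46, while IVL was at -0.20 (not called, adjusted p = 0.415). MKI67 rose by 0.53 ± 0.12 and EGFR by 0.59 ± 0.09, and HBEGF fell by 1.64. DUSP6 (0.11), KRT14 (-0.03) and KRT5 (-0.11) were not called. CEACAM5 and CEACAM1, relatives of CEACAM6 chosen after their values were seen, rose by 0.89 and 1.14, and CEACAM7 was at 0.31 (not called, adjusted p = 0.103).

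Wound response and migration genes rose in 16 of 26 (17 adjusted over the list alone, median 0.55, adjusted p = 1.82e-11, and 0.0485 with an estimated correlation). Genes of the epithelial to mesenchymal transition rose in 8 of 18 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 1.81e-05, and 0.0476 with an estimated correlation), with FN1, which encodes fibronectin, at 1.58. Suprabasal keratins and early differentiation genes fell in 14 of 25 (14 fell and 1 rose adjusted over the list alone, median -0.44, adjusted p = 2.56e-08, and 0.00272 with an estimated correlation), among them KRT77 (-1.60). Epidermal lipid barrier genes fell in 15 of 29 and rose in 2 (18 and 2 adjusted over the list alone, median -0.34, adjusted p = 2.46e-08, and 0.000568 with an estimated correlation), with LIPM at -2.01. Differentiation transcription factors fell in 9 of 25 (12 fell and 1 rose adjusted over the list alone, adjusted p = 0.000285, and 0.0283 with an estimated correlation), including TFAP2C (-0.81) and CEBPB (-0.81). G2 and M phase genes rose in 25 of 35 (30 adjusted over the list alone, median 0.53, adjusted p = 7.45e-13), with ANLN at 1.44 and DLGAP5 at 1.02. The test then gave adjusted p = 0.110 with an estimated correlation. S phase and DNA replication genes rose in 7 of 39 and fell in 2 (9 and 3 adjusted over the list alone, median 0.15, adjusted p = 0.0222). This call had adjusted p = 0.276 with an estimated correlation. It was also lost with quantile normalization (0.0587), without the dimmest 25% (0.0507) or dimmer 50% of genes (0.270), and without EGF_100 replicate 4 (0.067). Basal keratinocyte and hemidesmosome genes rose in 12 of 22 and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 1.11e-06), with KRT15 at 1.46 and ITGB4 at 1.43. The list had adjusted p = 0.0932 with an estimated correlation. Interferon response genes rose in 15 of 27 and fell in 2 (15 and 2 adjusted over the list alone, median 0.60, adjusted p = 4.08e-06). This call had adjusted p = 0.110 with an estimated correlation. Heat shock and unfolded protein response genes fell in 10 of 21 and rose in 4 (11 and 4 adjusted over the list alone, adjusted p = 3.36e-05). The test then gave adjusted p = 0.110 with an estimated correlation. Among members open to the naming rule the largest falls were those of ASNS (-2.27), which makes asparagine, and CHAC1 (-2.04), which degrades glutathione. Of 47 cornified envelope genes 12 rose, 11 fell and 24 were not called (13 and 12 adjusted over the list alone, median 0.05, mean -0.04, adjusted p = 0.869), and of 20 kallikreins and their inhibitors 2 fell and 18 were not called (2 adjusted over the list alone, median 0.03, mean -0.06, adjusted p = 0.642). In all 3713 genes were called, 1729 higher and 1984 lower with EGF. The higher genes were the more numerous with quantile normalization (2089 of 4054). The count was 1683 for changes of at least 1.5-fold, 6063 with array weights and 2053 with the authors' two-way layout and Tukey tests.

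The interaction tests whether the EGF change differed between the densities, and is given as the change at 100% minus that at 50% confluence. Among the genes open to the naming rule, CEACAM6 had the largest positive difference (4.72 ± 0.31, adjusted p = 1.01e-07). It was followed by IFIT1 (3.21), IFIT3 (2.46), MIR95 (2.34), whose levels were low in all groups, and the WNT antagonist gene DKK1 (2.23). The largest negative differences among the genes open to the rule were those of STC2 (-4.59 ± 0.52, adjusted p = 2.12e-05), LORICRIN (-3.92), SLC7A11 (-3.77), ARG1, which encodes arginase (-3.26), and CD36 (-3.24). At 50% confluence the means of LORICRIN (5.11 in vehicle), ARG1 (4.63) and CD36 (3.96) lay well below those in confluent vehicle cells, and whether a lower limit of detection hid a fall there was not measured. HBEGF rose by 0.79 with EGF at 50% and fell by 1.64 at 100% confluence, a difference of -2.43 (adjusted p = 1.39e-07). TGM1 and IVL differed the other way, by 1.26 and 1.01, with changes of -1.73 and -1.21 at 50% against -0.46 and -0.20 at 100% confluence. The differences of KRT10 (0.40, adjusted p = 0.159), KRT14 (-0.08) and KRT5 (-0.14) were not called. For interferon response genes 15 of 27 differed, all higher (16 adjusted over the list alone, median 0.79, adjusted p = 1.74e-11, and 0.0441 with an estimated correlation). Of 21 heat shock and unfolded protein response genes 10 were lower and 2 higher (12 and 2 adjusted over the list alone, median -0.50, adjusted p = 9.74e-09, and 0.0477 with an estimated correlation). Among 29 lipid barrier genes 10 were lower and 1 higher (12 and 3 adjusted over the list alone, adjusted p = 0.0015, and 0.0441 with an estimated correlation), and among 18 genes of the epithelial to mesenchymal transition 7 were higher (9 adjusted over the list alone, adjusted p = 1.49e-06, and 0.0441 with an estimated correlation). For G2 and M phase genes 14 of 35 were higher (26 adjusted over the list alone, adjusted p = 1.55e-14). The list had adjusted p = 0.0774 with an estimated correlation. The interaction called 1677 genes, 807 higher and 870 lower, and 3358 with array weights. The higher genes were the more numerous with quantile normalization (1050 of 1955), with all rows (892 of 1702), and without vehicle_50 replicate 1 (743 of 1424) or replicate 2 (747 of 1473). The same held without EGF_50 replicate 2 (667 of 1280) or replicate 4 (723 of 1339), vehicle_100 replicate 3 (649 of 1281), or EGF_100 replicate 2 (795 of 1569) or replicate 3 (961 of 1874).

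**Figure D3:**
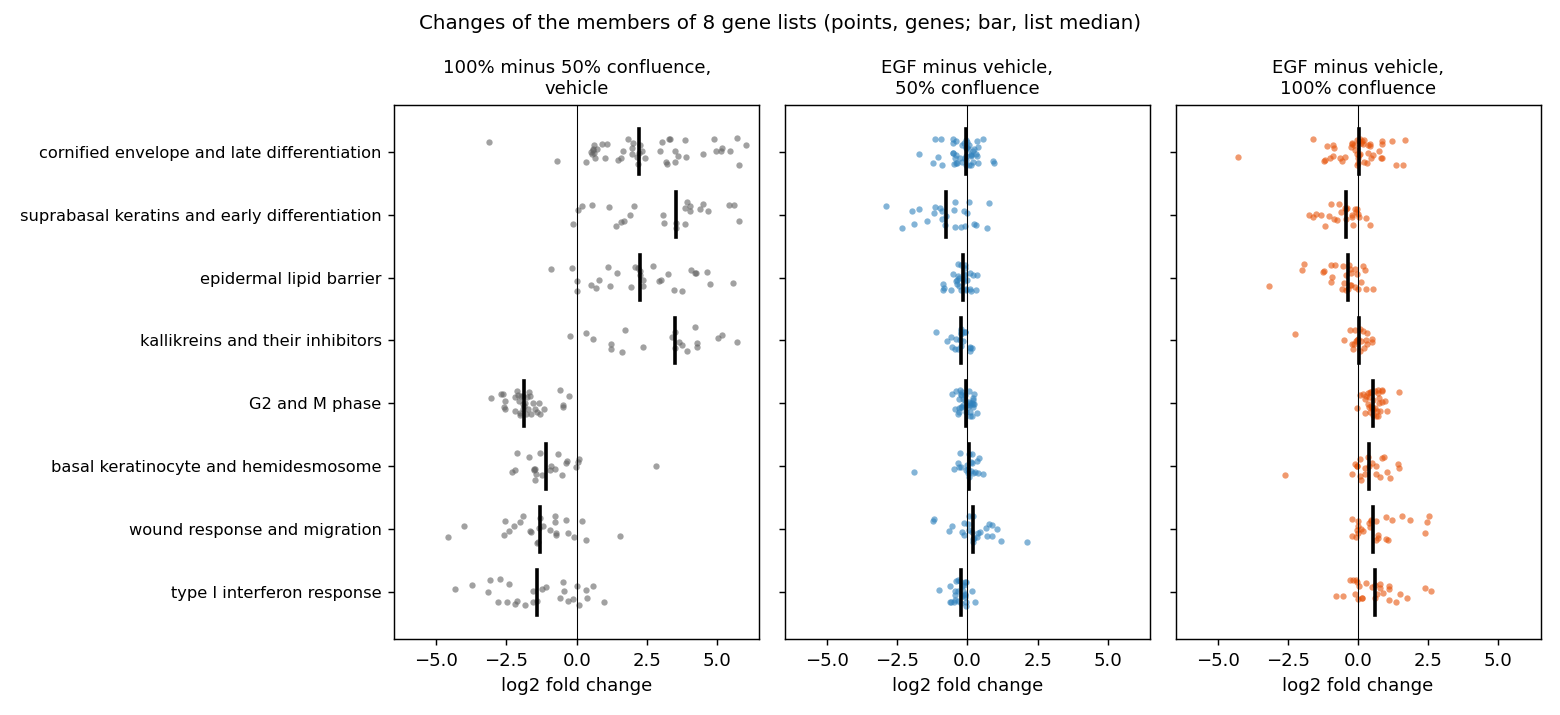
Log2 change (x axis) of each measured member (points) of 8 gene lists for density in vehicle, EGF at 50% confluence and EGF at 100% confluence; bars mark the list median. G2 and M phase genes had a median of -1.87 for density in vehicle and 0.53 for EGF at 100% confluence.

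Many genes that moved with density moved the other way with EGF in confluent cells. Of the 3816 genes higher in confluent vehicle cells, 1282 (33.6%) fell and 88 rose with EGF at 100% confluence, where independent calls would share 411 and 358. Of the 3699 genes lower in confluent vehicle cells, 1309 (35.4%) rose and 103 fell, where independent calls would share 347 and 398. VIM, THBS2 and TFPI2 were among the latter, with density changes of -4.02, -3.74 and -4.58 and EGF rises of 2.47, 1.20 and 1.84, and SPTSSB was among the former, with a density change of 5.78 and an EGF change of -2.71. The median EGF change was -0.22 for the genes that rose with density (median density change 0.62) and 0.24 for those that fell (median density change -0.68). Across genes, which are not independent replicates, the 2 contrasts had Pearson r = -0.57 and Spearman rho = -0.51, but they share the confluent vehicle arrays. Simulated unchanged groups gave r = -0.50. They hold no density or EGF change, so this r is not the part of the observed r due to sharing. In the 6 splits in which the contrasts share no array, the mean r was -0.53 (-0.59 to -0.48). The covariance was -0.161, against -0.0139 in the simulated groups, and -0.154 ± 0.00821 (SD) over the 6 splits in which the contrasts share no array. In those splits, which use fewer arrays, 27.3% of the genes that rose with density fell with EGF and 25.7% of those that fell rose. Among the 4 relations between contrasts, the EGF changes at 50% and 100% confluence, which share no array, had r = 0.32 and rho = 0.28 across genes; 248 genes rose and 209 fell at both densities, where independent calls would share 64.8 and 61.7. The share of genes that fell with density and rose with EGF was 21.4%, and that of genes that rose with density and fell with EGF 31.1%, when changes of at least 1.5-fold were required, a setting chosen for the shares after seeing the data.

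**Figure D4:**
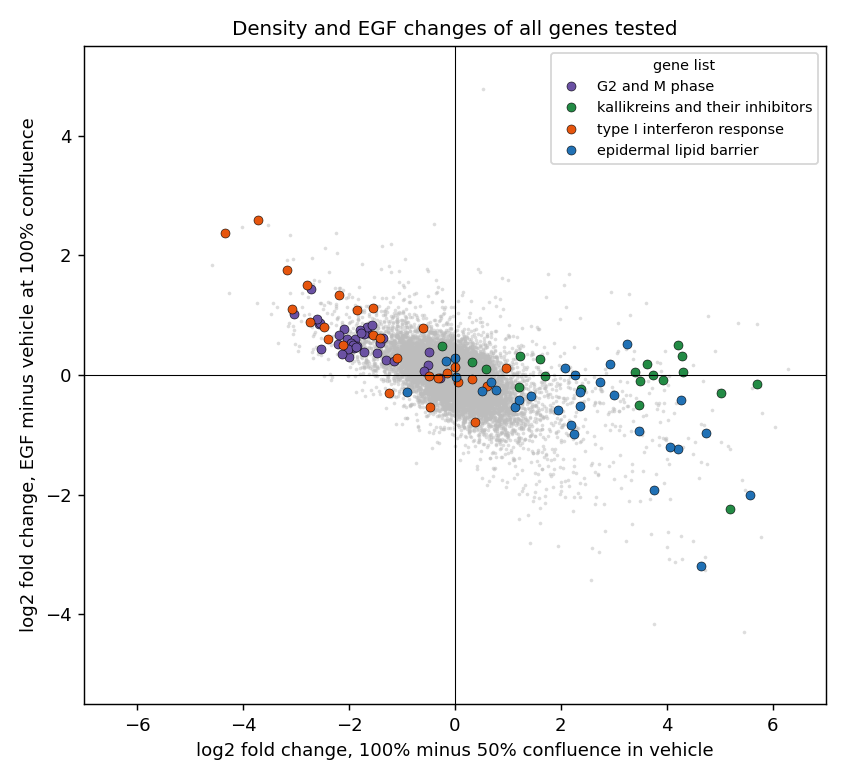
Log2 change with EGF at 100% confluence (y axis) against log2 change with density in vehicle (x axis) for all 18417 genes, with 4 gene lists in colour. Pearson r across genes was -0.57. Simulated groups without any density or EGF change, which share the confluent vehicle arrays between the axes, gave r = -0.50. In the 6 splits in which the axes share no array, the mean r was -0.53.

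Of 12 melanocyte markers 4 rose with density in vehicle (4 adjusted over the list alone, median 0.36, adjusted p = 0.0487), with PMEL at 0.77 and GPM6B at 0.61. This call had adjusted p = 0.393 with an estimated correlation. That call was also lost with quantile normalization (0.0883), with 16 added (0.057), without the dimmest 25% (0.145) or dimmer 50% of genes (0.55), and without vehicle_50 replicate 1 (0.0503), replicate 3 (0.0727) or replicate 4 (0.0567), EGF_50 replicate 4 (0.0505), vehicle_100 replicate 1 (0.0587) or replicate 3 (0.058), or EGF_100 replicate 3 (0.0522). Fibroblast markers fell with EGF at 50% confluence in 3 of 14 (5 adjusted over the list alone, adjusted p = 0.000805, and 0.0343 with an estimated correlation), with DCN at -1.45 and MFAP5 at -0.58, and with density 4 rose and 4 fell (adjusted p = 0.708). For 15 leukocyte and Langerhans cell markers, 3 rose with density (2 adjusted over the list alone, median 0.27, adjusted p = 0.181). Of these markers CD68 rose by 1.39 and TYROBP fell by 0.97 with EGF at 100% confluence, and the fibroblast marker DCN was at -1.37 there, all named after their values were seen. For the 12 endothelial markers the list test gave adjusted p = 0.454 for density in vehicle, and 12 of 12 were not called there.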

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

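The tests of chance by permuted residuals, of a uniform partial reversal, of a single aberrant array, of chaperone genes and of leukocyte markers, and the list tests without dim genes, were chosen only after the result was seen.

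Of 380 groups of 4 values, from 94 named genes and the array medians, 27 held 1 array far from the other 3; chance alone gives this in about 1 in 20 groups. In vehicle_100 replicate 2 these were FLG2 (log2 value 11.66), SPTSSB (10.42), EPGN (8.26), SLC7A11 (10.84), RORA (10.48), INSIG1 (9.11) and CEBPB (9.26). In EGF_100 replicate 3 they were DSG1 (12.04), MMP10 (7.69), S100A7 (9.87) and ZNF750 (8.74). In EGF_100 replicate 2 they were G0S2 (8.45) and FN1 (12.52), and in EGF_100 replicate 4 KRT5 (13.84). In vehicle_100 replicate 4 they were MKI67 (6.44) and SLPI (13.45), and in vehicle_100 replicate 1 LORICRIN (10.42). Among the subconfluent arrays they were DCN (7.22) and MFAP5 (11.35) in vehicle_50 replicate 1, ROCK1P1 (4.6) and CERS3 (9.45) in vehicle_50 replicate 2, CXCL14 (10.67) in vehicle_50 replicate 3, SPTSSB (5) and CEACAM6 (4.94) in vehicle_50 replicate 4, and G0S2 (10.39), RORA (5.99) and DCN (5.39) in EGF_50 replicate 1.

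The EGF change differed between the densities by the interaction test for many named genes, given as the log2 change at 100% minus that at 50% confluence. Among the differentiation genes the difference was -1.26 for KRT1, 1.01 for IVL, -3.92 for LORICRIN, -0.84 for FLG, 1.26 for TGM1, -1.0 for FLG2, -0.88 for KRT23, -0.97 for HOPX, -1.39 for KRT77, 2.21 for DSG1, 0.85 for DSC1, 1.21 for CRABP2, 1.40 for CLDN1 and 1.40 for DSC2. Among lipid, protease and barrier genes it was -2.37 for SPTSSB, -2.37 for LIPN, -1.72 for LIPM, -0.94 for SDR9C7, 0.88 for SULT2B1, -1.97 for SERPINB12, 0.92 for KLK5, 0.65 for SLPI and 1.10 for FADS2. Transcription factors TFAP2C and CEBPB gave -0.73 and -1.10. Growth, basal and wound genes gave 0.87 for MKI67, 0.64 for EGFR, -2.43 for HBEGF, -0.62 for DUSP6, -0.84 for PHLDA1, -1.18 for INHBA, 1.10 for DLGAP5, 1.28 for ANLN, 0.92 for TYMS, 0.96 for MCM6, 0.59 for ITGA2, 1.31 for KRT15, 1.25 for ITGB4, 0.95 for TFPI2, 1.60 for MMP10, 1.58 for VIM, 1.39 for FN1, 0.68 for SPARC, 1.59 for NT5E, 1.10 for EMP3 and 1.08 for THBS2. Interferon-induced genes gave 3.21 for IFIT1, 2.46 for IFIT3 and 1.90 for IFI44L. Other genes gave 4.72 for CEACAM6, 2.34 for MIR95, 2.23 for DKK1, 2.19 for CXCL14, 0.85 for HMOX1, -0.75 for SLC6A14, -1.63 for G0S2, -1.32 for TMEM200A, -2.84 for THAP3, -3.24 for CD36, -3.26 for ARG1, -4.59 for STC2, -3.77 for SLC7A11, -2.65 for ASNS, -2.11 for CHAC1, -1.66 for HERPUD1 and -1.0 for HSPA5. The DUSP6 call was lost without vehicle_50 replicate 1, 2 or 4, EGF_50 replicate 2, 3 or 4, vehicle_100 replicate 1, 3 or 4 or EGF_100 replicate 1, 3 or 4 (adjusted p from 0.0637 to 0.103). The HOPX call was lost without vehicle_50 replicate 2, 3 or 4, EGF_50 replicate 2, 3 or 4 or any vehicle_100 array (0.0569 to 0.0861), and the ITGA2 call without vehicle_50 replicate 1, 3 or 4, any EGF_50 or vehicle_100 array, or EGF_100 replicate 1 or 2 (0.065 to 0.102). The SLC6A14 call was lost without vehicle_50 replicate 2, EGF_50 replicate 2 or 4, vehicle_100 replicate 2 or EGF_100 replicate 1 (0.054 to 0.0614), and the KRT23 call without vehicle_50 replicate 1, EGF_50 replicate 2 or 3 or vehicle_100 replicate 2 or 4 (0.054 to 0.0586). DLGAP5 was lost without vehicle_100 replicate 2 (0.05), SPARC without vehicle_100 replicate 2 (0.051) and PHLDA1 without vehicle_100 replicate 4 (0.0514). Under other settings, DUSP6 was lost with quantile normalization (0.0573), median centring (0.0544) and all rows (0.0789), and ITGA2 with median centring (0.0822) and all rows (0.0838). HOPX was lost with 16 added (0.0535), quantile normalization (0.0637) and all rows (0.0774), and SLC6A14 with 16 added (0.0752), quantile normalization (0.121) and all rows (0.0511). TFPI2 was at 0.44 with 16 added and lost its call (0.233), KRT23 was lost with all rows (0.0569) and SPARC with median centring (0.0544).

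The list test gave the same kind of difference for 16 lists, with these medians: cornified envelope and late differentiation 0.14, epidermal lipid barrier -0.28, desmosomes and tight junctions 0.13, kallikreins and their inhibitors 0.32, basal keratinocyte and hemidesmosome 0.36, G2 and M phase 0.60, S phase and DNA replication 0.22, EGFR and ERK feedback targets -0.17, wound response and migration 0.41, type I interferon response 0.79, cholesterol synthesis -0.21, YAP and TAZ targets 0.22, aryl hydrocarbon receptor targets -0.19, heat shock and unfolded protein response -0.50, epithelial to mesenchymal transition 0.42 and fibroblast markers 0.17. With an estimated correlation the lipid barrier, interferon, unfolded protein response and mesenchymal transition lists passed, and the others had adjusted p from 0.0637 to 0.455. The cornified envelope call was lost without vehicle_50 replicate 2 (adjusted p = 0.0675) or replicate 4 (0.0875), EGF_50 replicate 4 (0.0633), vehicle_100 replicate 1 (0.0566), or EGF_100 replicate 2 (0.0652), replicate 3 (0.0749) or replicate 4 (0.0504). The cholesterol synthesis call was lost without EGF_100 replicate 2 (0.063) and the fibroblast call without EGF_100 replicate 3 (0.0751). Quantile normalization ended the cholesterol synthesis call (0.0667) and the fibroblast call (0.0667). Leaving out the dimmest 25% of genes ended the cornified envelope (0.0693) and fibroblast calls (0.191), and leaving out the dimmer 50% the aryl hydrocarbon receptor (0.0727) and fibroblast calls (0.150). Outside the genes tested, 469 of the 13792 table rows that name no single gene were called higher with EGF at 100% confluence, and 611 lower.

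Other splits of the arrays tested whether chance groupings of the same samples give counts as large. Of the 35 splits of 8 arrays into 4 and 4, only 1, the real one, gave as many genes in each comparison. The counts were 8046 for density in vehicle (highest other split 0) and 4485 for density with EGF (43). They were 917 for EGF at 50% confluence (1) and 3629 for EGF at 100% confluence (0). With 35 splits the real one can stand out no further than 1 in 35. The other splits mix arrays of the groups compared, which by itself lowers their counts. Since no label says whether replicates are separate cultures, the splits cannot exclude a chance difference between the cultures of the groups. For the interaction, 2 of 100 relabellings of EGF and vehicle within each density, the real one included, gave as many genes (real 1677, highest other 1681). The relabelling with 1681 kept all 8 arrays at 100% confluence as labelled or mirrored. Such relabelling also removes the EGF effect at a density, so it cannot test the difference between densities against chance. Permuting the residuals of a fit without interaction over the 16 arrays keeps both effects. Of 100 draws, the real one included, only 1 gave as many genes (real 1677, highest other 14). The draws take the arrays as equally variable, though array weights ran from 0.262 (EGF_100 replicate 3) to 3.58 (vehicle_100 replicate 3). Random spread of that kind thus rarely gave this count, but a chance difference between cultures cannot be excluded.

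The first pattern weighed is the movement back of density genes with EGF at 100% confluence. Noise of single confluent vehicle arrays, shared by the contrasts, is argued against as the whole source. The mean covariance over the 6 splits without a shared array was -0.154 (SD 0.00821). The splits reuse the same 4 arrays, so this SD is not a sampling error. A deviation common to all 4 confluent vehicle arrays, as from a shared culture, would stay in every split. Such a common deviation was not tested and stays open. A shift back by 1 shared fraction of the log2 change is argued against for the fixed genes. Of the 10 called by density, 5 lay over 3 SE from the best shared reversed fraction of 0.262. LORICRIN was at 0.783 and FLG at 0.108. The difference of 0.305 between G2 and M phase genes and kallikreins, 2 lists picked by their values, cannot decide whether the fraction is shared. A return of a share of the cells to the subconfluent state need not give equal log2 fractions. Such a return was not tested and stays open. Limits of bright or dim probes, which were not measured, could also make the fractions unequal. With quantile normalization 37.1% of the rising and 37.7% of the falling genes were reversed. The EGF added to confluent cells, a factor the design varies, may account for the pattern and stays untested as a mechanism. Whether EGF receptor signalling changed in these cells was not measured. DUSP6 (0.11) and PHLDA1 (0.005), feedback targets called with EGF at 50% confluence, were not called with EGF at 100% confluence.

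The second pattern is the rise with density in vehicle and fall with EGF at 100% confluence of 9 amino acid response genes, namely STC2, SLC7A11, ASNS, CHAC1, CTH, DDIT3, PCK2, PSAT1 and TRIB3, chosen after their values were seen. Amino acid response genes not inspected before had a median EGF change at 100% confluence of -1.01 (95% bootstrap interval -1.29 to -0.85), and 27 of 30 fell. Their median density change was 0.67, so a shared amino acid response program is a candidate explanation. The bootstrap intervals here and below resample the genes of a list, which are not independent, and not the arrays. They do not measure the error of a density or EGF effect between samples. Endoplasmic reticulum stress that raises chaperone genes as a set is argued against, since 14 chaperone genes had a median density change of -0.48 (-0.94 to -0.27), and the 10 of them outside the fixed lists -0.48 (-0.95 to -0.15). With density in vehicle 9 of the 14 fell and 1, DNAJB9, rose (0.97). Stress without a rise of chaperones as a set cannot be judged from these genes. A single aberrant array is argued against, since each confluent array alone gave a median EGF change of -0.76 or lower for the genes not inspected before. Whether the medium of the confluent vehicle cells lacked an amino acid was not measured.

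The third pattern is the fall with density in vehicle and rise with EGF at 100% confluence of interferon response genes. For the rise, the list call was lost with an estimated correlation between genes. Interferon genes outside the fixed list had a median density change of -1.47 (-1.64 to -1.22; 23 of 26 fell), so a wider interferon program in the subconfluent cells is a candidate explanation. Leukocytes numerous enough to raise their markers in the subconfluent cells are argued against. Leukocyte and Langerhans cell markers had a median density change of 0.265 (0.115 to 0.323), not below 0. Whether a small share of leukocytes would move these markers was not measured, so such a share stays open. What induced the genes stays open, and the biological factors of density and EGF were not separated from it.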

How the results depend on the processing

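The recomputed correlation between the EGF changes, the list tests with array weights, with 16 added or without dim genes, and the shares of reversed genes with the fold threshold, median centring, 16 added, a variance trend, array weights or the dimmest 25% left out were tests chosen only after the result was seen. No named gene or list that was called in the main fit or in an alternative reversed its direction between them. Sign changes of results called in neither were not counted. Whether more genes were higher or lower turned with the settings named beside the counts. Requiring at least 1.5-fold gave 4295 genes for density in vehicle, 2879 for density with EGF, 565 for EGF at 50% and 1683 for EGF at 100% confluence, since fewer genes can pass. The share of falling genes that rose with EGF was then 21.4% and that of rising genes that fell 31.1%; the cause was not tested. Array weights gave 9071 for density with EGF, 3112 for EGF at 50%, 6063 for EGF at 100% and 3358 for the interaction; the cause was not tested. The two-way layout with Tukey tests gave 4112 for density in vehicle and 2053 for EGF at 100%. It tests fewer genes and also uses a test without moderation, and which of these lowered the counts was not tested. Leaving out 1 array gave 6502 to 7963 genes for density in vehicle, 4329 to 6960 for density with EGF, 625 to 1941 for EGF at 50%, 2840 to 4415 for EGF at 100% and 1234 to 1957 for the interaction. For EGF at 50% the count was 748 without vehicle_50 replicate 1, 780 without vehicle_50 replicate 3, 719 without EGF_50 replicate 2, 625 without EGF_50 replicate 3, 764 without EGF_50 replicate 4 and 1941 without EGF_100 replicate 3. The share of rising genes that fell with EGF was 28.4% to 37.3%, that of falling genes that rose 28.5% to 39.2%, and r between the EGF changes 0.258 to 0.382. Among 135 list results, 37 calls were lost with an estimated correlation, 6 with quantile normalization, and 5 and 9 without the dimmest 25% and dimmer 50% of genes. The 135 include lists that were not called, so the share of calls lost is larger than these counts over 135. A block on replicate number, which the labels do not make a pair, gave 7733, 5788, 1220, 3755 and 1689 genes in the order above; arrays of one number were not consistently alike (r from -0.389 to 0.446). With the block the interaction calls of DUSP6 (adjusted p = 0.0637) and ITGA2 (0.0677) were lost. Saturation of bright probes, such as those of KRT14, KRT5, KRT10 and KRT1, and a lower limit of detection were not measured.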

Other observations

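The genes of the following lists were written after the main results had been seen, and the list tests with array weights or without dim genes were tests chosen only after the result was seen. Endoplasmic reticulum chaperones, 4 of them also in the fixed unfolded protein response list, rose in 8 of 14 and fell in 1 with EGF at 50% confluence (median 0.47, 95% bootstrap interval 0.22 to 0.66), and rose in 3 and fell in 4 with EGF at 100% confluence (median -0.02). The amino acid response genes not inspected before rose in 20 of 30 and fell in 1 with density in vehicle, and 2 rose and 19 fell with density in the presence of EGF (median -0.52). Interferon genes outside the fixed list fell in 20 of 26 with density in the presence of EGF (median -0.95) and rose in 11 with EGF at 100% confluence (median 0.39).

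Other fixed lists were not called for density in vehicle: EGFR and ERK feedback targets rose in 12 and fell in 12 of 35 (median 0.03; the test leaned down, adjusted p = 0.708), EGF family ligands and receptors rose in 7 and fell in 2 of 14 (adjusted p = 0.104), inflammatory cytokines and chemokines rose in 8 and fell in 4 of 25 (0.287), hypoxia and glycolysis genes rose in 9 and fell in 9 of 27 (median -0.03, mean 0.17; 0.905), p53 targets rose in 6 and fell in 6 of 19 (0.518), cholesterol synthesis genes rose in 3 and fell in 8 of 19 (0.0558), and heat shock and unfolded protein response genes rose in 11 and fell in 7 of 21 (0.203). For the cholesterol list the test passed with quantile normalization (adjusted p = 0.0408) and array weights (0.0262), and the adjusted p was 0.0244 without vehicle_50 replicate 2 and 0.0374 without vehicle_100 replicate 2. The list of aryl hydrocarbon receptor targets rose in 8 and fell in 2 of 13 with density in vehicle (adjusted p = 0.0258), with SLC7A11 at 2.575 and HMOX1 at 1.98. SLC7A11 is also among the amino acid response genes above, and activity of the receptor was not measured. The list had adjusted p = 0.0512 with an estimated correlation and 0.111 without the dimmer 50% of genes. ATF4, a transcription factor of the amino acid response chosen after its values were seen, rose by 0.87 with density in vehicle and fell by 1.38 with EGF at 100% confluence.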
